A study of Arabidopsis thaliana with 12 samples.

How the data were processed

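The series holds 12 Agilent arrays with 2 dyes, each of which compared RNA from the aerial parts of an Arabidopsis thaliana transformant line with RNA from the wild type Col-0. The titles name 6 lines, each carrying 1 rice full-length cDNA clone (AK069096, AK073112, AK073675, AK065297, AK102323 or AK073210), with 2 replicate arrays per line. Per the labels, plants grew at 22 °C with 16 h of light and 8 h of dark, RNA was extracted with an RNAqueous kit, and 1 µg of total RNA was amplified and labelled. In every label the transformant carries Cy3 and Col-0 carries Cy5, so no array swaps the dyes. Lines were taken from the titles and sample sources, because the descriptions of all 12 arrays repeat the clone name AK069096. Whether the 2 arrays of a line come from separate plants is not given in the sources used here, so the p-values measure the spread between arrays.

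The deposited values are 1 log ratio per probe and array for 21500 probes. The submitters' processing notes name Agilent Feature Extraction 7.1.1. The deposited table states no log base, and the values were taken as log10 ratios made by the authors, because they have the form of that program's log ratio column: signed, with a median of 0 on every array and between 2.92% and 9.43% of probes at exactly 0. They were put on the log2 scale. The p-values of the fits do not depend on the base. Every log2 value printed here does, and so does every count that uses a fixed cut-off in log2. The direction of the ratio is not given in the sources used here. The program's usual order of dyes would make it Col-0 over transformant, and the order of words in the titles would make it the reverse. Values are therefore given on the positive or the negative side of the deposited ratio, and never as higher or lower in the transformants. Channel intensities, the background method and the dye normalization are not given in the sources used here.

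Gene names came from the gene list for the array's probes, updated by gene ID to the symbols of the TAIR10.1 annotation. Of the 21500 probes, 9375 are listed with a gene, 9335 of them with 1 gene and 40 with several, and 12125 with none. By gene ID 9317 probes matched and 18 did not, and 1317 carry a symbol other than a locus code. Probes without a gene stayed in every test and count, but no gene list or family can hold them.

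Testing used limma 3.58.1 in R 4.3.3 on the 21494 probes with a value on all 12 arrays. A mean was fitted for each line with a spread shared by all lines (6 residual degrees of freedom, with 1.88 prior degrees of freedom from the moderation of the spread). The 13 comparisons were each line against Col-0 (its mean ratio against 0), each line against the mean of the other 5 lines, and all 6 lines together against Col-0. Tests were two-sided, with Benjamini-Hochberg adjustment over all probes of a comparison and a threshold of 0.05. A dye effect or a property of the Col-0 RNA that is common to all arrays stays in the comparisons with Col-0 and cancels between lines. A property of a Col-0 RNA used for the arrays of a single line would not cancel. With 2 arrays per line, neither an outlier test within lines nor a count over regroupings of 3 or more arrays could be made.

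Genes to name were fixed by a rule before the data were examined. For each line against Col-0 these are the 8 highest and 8 lowest probes past the threshold with both arrays on the same side and a gene symbol. For each line against the other 5 the rule takes 4 and 4, and for all 6 lines 6 and 6 with all 12 arrays on the same side. A gene of unknown function may be left out of the text. The rule gave 132 results for 76 genes.

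Also fixed beforehand were 21 gene lists for processes and organs of shoots. The array's named probes cover few of their members. The lists for abscisic acid and drought response, floral identity, seed storage and phosphate starvation have no named probe (4 lists), 9 lists have 1 or 2 genes and were read gene by gene, and 8 lists with at least 3 genes were tested as sets. Those 8 are photosynthesis (5 of 42 genes), chlorophyll synthesis (4 of 15), cold response (5 of 14), heat shock (7 of 20), root genes (3 of 14), flavonoid and anthocyanin synthesis (5 of 17), auxin response (3 of 21) and detoxification (3 of 13). The set test was limma's camera with a preset correlation of 0.01 between genes, beside camera with an estimated correlation and fry. After the gene list for the probes had shown this coverage, 11 gene families were added by symbol. A list of mature pollen and tapetum genes was written after the first results for AK073210.

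The fit was checked on simulated arrays of 6 lines with 2 arrays each, with 100 probes changed by a log2 of 1 and 100 by a log2 of 2. Each array was drawn independently, with no Col-0 or dye effect shared between arrays. The false calls below therefore do not cover such effects in the comparisons with Col-0. All lines also had the same spread at a given probe. In the data the AK073112 replicates correlated at 0.352, the lowest within a line. Recovery and false calls under unequal spread between lines are not covered either. For AK069096 against Col-0 it recovered 69 and 96 of these among 21494 probes, with 9 false calls. Over the 13 comparisons it recovered from 57 (AK069096 against the other 5 lines) to 97 at a log2 of 1 and from 88 to 100 at a log2 of 2, with 6 to 19 false calls. The 19 were for AK065297 against Col-0, beside 73 and 95 recovered. Of 100 simulated lists of 5 probes 20 were shifted, and all 20 were recovered for AK069096 against Col-0, with 1 false call among the unshifted lists. Probes in these lists were drawn independently. The flavonoid, photosynthesis and chlorophyll lists had estimated correlations of 0.42, 0.81 and 0.93, which this check does not cover.

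Alternatives fixed beforehand were centring each array on its median (which moves nothing, since every median is already 0), quantile normalization across arrays, a replicate block, a robust spread, array weights, probes with missing values kept (which adds the 6 probes absent from 2 arrays), ratios of exactly 0 treated as missing, probes averaged per locus (9248 loci), an added minimum log2 ratio of 1, only the 2 arrays of the line, and each array left out in turn. Leaving out both AK073112 arrays was added after the data were seen. Arrays of a line would have had their signs compared if they had correlated below -0.3, and none did. Turning the sign of all arrays only exchanges the sides. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.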

Results

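Transcript ratios against Col-0 were measured in 6 Arabidopsis lines, each transformed with a different rice full-length cDNA clone and named here by that clone. Each line has 2 arrays, 12 in all, with 21494 probes tested. What the 6 rice cDNAs encode is not given in the sources used here. Values are log2 ratios as deposited, whose direction between transformant and Col-0 is not settled, and errors are the SE of the fit unless named otherwise. Genes are ranked among the 1317 of 21500 probes with a gene symbol, and probes known only by a locus code or by no gene are left out of that ranking. The standard deviation of the ratios over probes ran from 0.40 on AK102323 replicate 2 to 0.68 on AK073112 replicate 2.

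**Figure D1:**
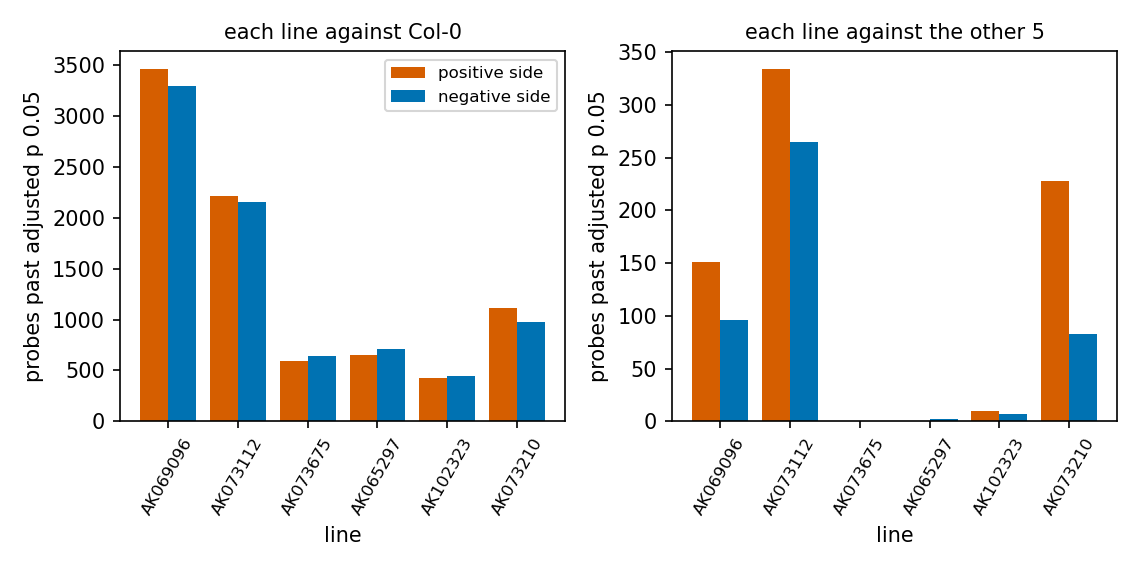
Number of probes past an adjusted p of 0.05 (y axis) for each line (x axis), with bars for the positive and the negative side of the deposited ratio. Left, each line against Col-0, from 870 probes in AK102323 to 6763 in AK069096; right, each line against the other 5 lines, from 0 in AK073675 to 599 in AK073112.

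The comparison of all 6 lines with Col-0 addresses what the transformants share. In it 50.9% of all probes passed, the share beside which counts of genes past the threshold stand. Among genes with a symbol, those of anthocyanin synthesis lay farthest on the positive side. DFR, the dihydroflavonol reductase of the pathway, had a log2 ratio of 3.68 ± 0.25 (n = 12 arrays, adjusted p = 4.54e-05), and UF3GT, which adds xylose to anthocyanins, one of 3.67 ± 0.21 (n = 12, adjusted p = 2.69e-05). The anthocyanin malonyltransferase gene AT5MAT stood at 2.77, the flavonoid glucosyltransferase gene UGT78D2 at 1.86, and the anthocyanin glucosyltransferase gene AT4G14090 at 1.68 on one of its probes and at -0.09, not past the threshold, on the other. On the negative side the farthest named gene was MSRB6, a methionine sulfoxide reductase gene, at -2.80 ± 0.24 (n = 12, adjusted p = 0.000103). Among genes with a symbol and all 12 arrays on one side it was followed by CYP79A2, whose enzyme makes phenylacetaldoxime from phenylalanine, at -1.16, the beta-glucosidase gene BGLU16 at -1.13 and PORB, a protochlorophyllide reductase gene, at -1.09.

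As a set, 5 of the 6 flavonoid and anthocyanin probes passed on the positive side; adjusted over the list alone the sixth, the second probe of AT4G14090, also passed, on the negative side. The list's mean was 2.26 (camera adjusted p = 0.00739; adjusted p = 0.445 with an estimated correlation), positive on 12 of 12 arrays. All 4 chlorophyll synthesis genes passed on the negative side, over all probes and adjusted over the list alone: PORB, the methyltransferase gene CHLM at -0.73, HEMB1 at -0.67 and GSA1 at -0.31, genes of early tetrapyrrole synthesis. Their mean was -0.70 (adjusted p = 0.00739; adjusted p = 0.445 with an estimated correlation), negative on 12 of 12 arrays. In the photosynthesis list 4 of 5 genes passed on the negative side, by either adjustment: the photosystem I genes PSAE-1 at -0.79 and PSAN at -0.55 and the antenna genes LHCB4.2 at -0.59 and LHCB4.1 at -0.48. RCA, the Rubisco activase gene, stood at -0.04. The list's mean was -0.49 (adjusted p = 0.0323; adjusted p = 0.52 with an estimated correlation), negative on 11 of 12 arrays and positive on AK073112 replicate 1. None of these medians changed side under quantile normalization.

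**Figure D2:**
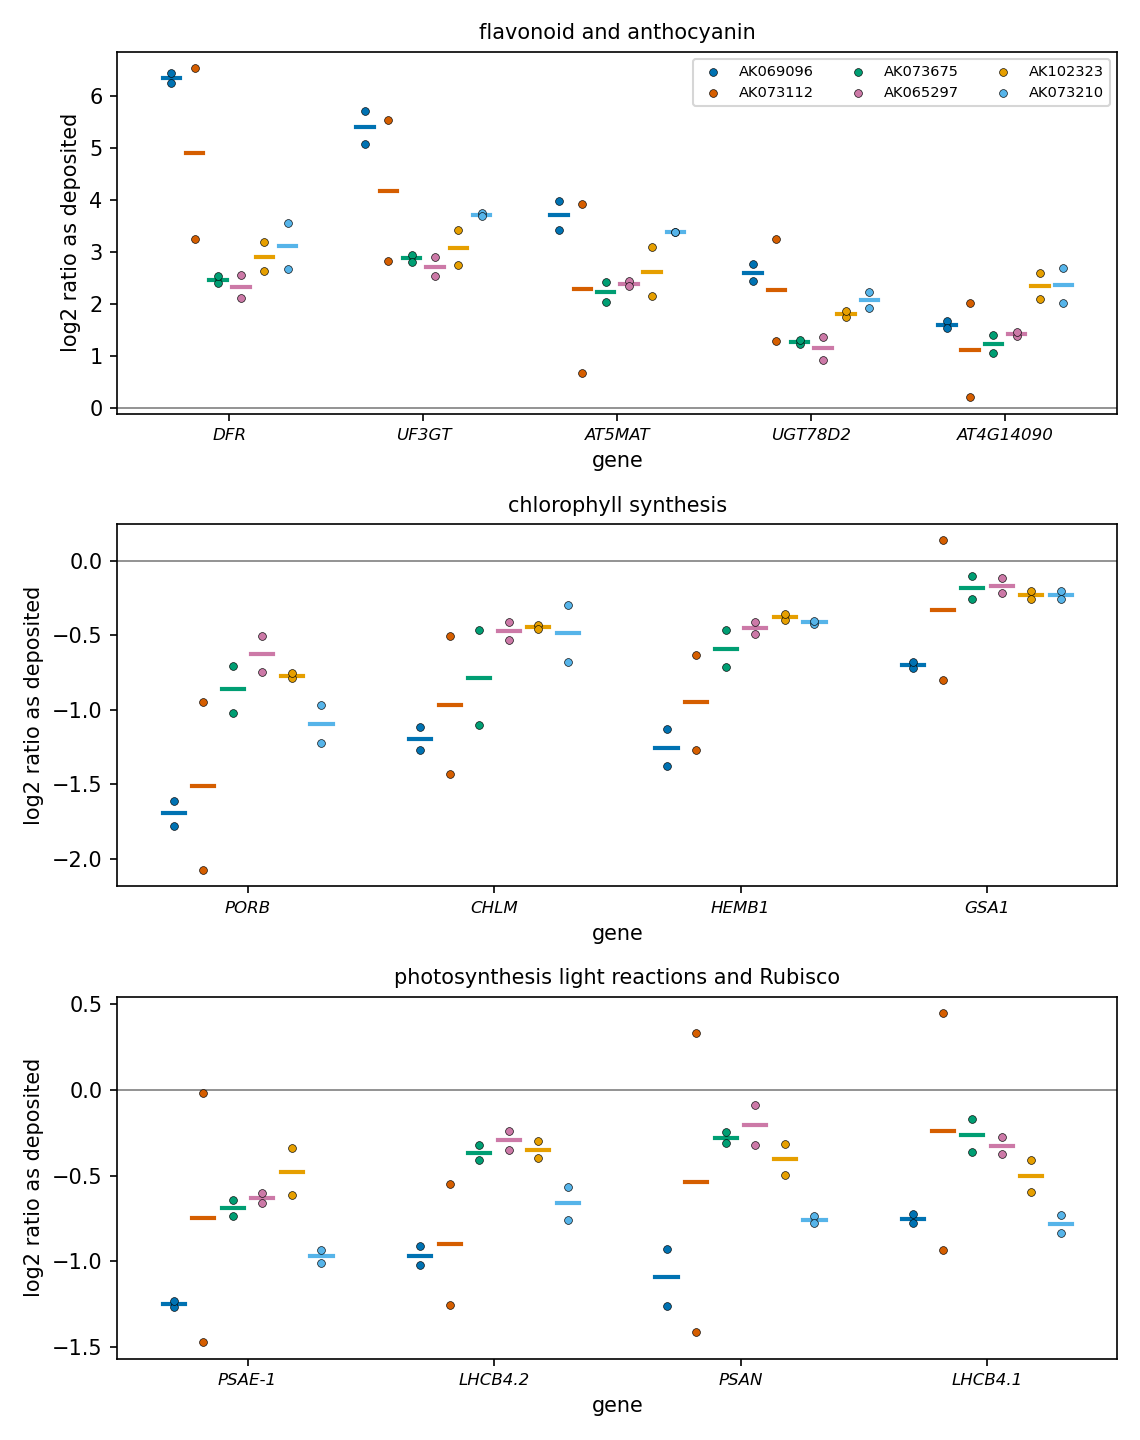
Log2 ratios as deposited (y axis) of the flavonoid, chlorophyll and photosynthesis genes past the threshold for all 6 lines (x axis), with a point for each array, coloured by line, and a bar at each line's mean. DFR lies above 2 on all 12 arrays and PORB below -0.50 on all 12, and the pair of AK073112 points stands far apart.

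Further genes on the positive side in all 6 lines included BETA-VPE, a vacuolar processing protease gene (2.24), NRT2.5, a high-affinity nitrate transporter gene (2.01), and SWEET13, a sucrose exporter gene (1.88). The transcription factor gene BZIP61 (-1.08) and the cold-regulated gene COR15B (-1.0) lay on the negative side. The cold response list went both ways, with COR15B and KIN1 (-0.24, negative on 8 of 12 arrays) against COR15A (0.74), and did not pass by camera (adjusted p = 0.619) but did by fry (adjusted p = 0.00169), with 3 genes past the test by either adjustment. Heat shock genes also split, 2 on each side (adjusted p = 0.814; 4 genes adjusted over the list alone), as did auxin response, with IAA29 at -1.34 and GH3.1 at 0.52 (adjusted p = 0.814; 2 genes adjusted over the list alone). The root list (EXPA18 at 0.48; adjusted p = 0.814; mean 0.04 and median -0.15) and detoxification (UGT73B5 at 0.76; adjusted p = 0.239, by fry 6.99e-05) had 1 gene each past the test by either adjustment.

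Of the lists with 1 or 2 measured genes, several held genes past the threshold for all 6 lines. On the positive side were SAG29, a senescence-associated sugar transporter gene (1.19), the senescence regulator WRKY6 (0.38) and the rapid stress zinc finger gene STZ (0.68). The jasmonate-responsive thionin gene THI2.1 (0.25) and the pollen gene VGD1 (0.57) passed as means of all lines, but these rest on AK073210, with 2.58 and 3.85 there and -0.21 and -0.08 in the mean of the other lines. On the negative side were the salicylic acid pathway genes WRKY53 (-0.58) and GRX480 (-0.39, negative on 9 of 12 arrays), the clock gene GI (-0.29), the replication gene PRL (-0.48), the glucosinolate genes UGT74B1 (-0.53) and BCAT4 (-0.25, negative on 8 of 12 arrays) and the iron regulator BHLH101 (-0.44, negative on 9 of 12). PDF1.2 at 0.42, the anther gene AT5G07230 at -0.02 and PYE at 0.09 did not pass.

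In this comparison 10944 of 21494 probes passed, 5681 on the positive and 5263 on the negative side, and 411 of them had an absolute log2 ratio of at least 1. In the comparisons of single lines with Col-0, 86 probes passed on the positive side in all 6 lines. On the negative side 80 passed in all 6, together 166. Every array was set against Col-0, whose own spread no array measures. In 20 simulations of unchanged lines against 1 Col-0 sample with the spread of the arrays, a median of 9725 probes passed for all lines together (9614 to 9904) and 27 in every line on one side (20 to 40), both below the observed 10944 and 166. Probes with every array on one side, 3222, were not above the simulated 3239 to 3386, and the median covariance between arrays of different lines, 0.109, lay within the simulated 0.104 to 0.115. Their median correlation, 0.431, lay below the simulated 0.487 to 0.514.

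AK069096 had the most probes past the threshold against Col-0. Anthocyanin genes again included the farthest with a symbol, with DFR at 6.34 ± 0.62 (n = 2 arrays, adjusted p = 0.000864), UF3GT at 5.40 and AT5MAT at 3.70. NRT2.5 stood at 4.17, SWEET13 at 3.84, the protease genes BETA-VPE at 3.82 and GAMMA-VPE at 3.31, and SHN3, a regulator of cuticle formation, at 3.21. On the negative side were MSRB6 at -4.04 ± 0.59 (n = 2, adjusted p = 0.00302), the expansin gene EXPA8 at -2.54, BGLU16 at -2.31, UGT73B1 and BZIP61 at -2.18, AKINBETA1, a subunit gene of the SnRK1 kinase, at -2.05, the thionin gene THI2.2 at -1.95 and PSB27, a photosystem II assembly gene, at -1.85. All 4 chlorophyll synthesis genes passed on the negative side (mean -1.21, camera adjusted p = 0.00773; adjusted p = 0.619 with an estimated correlation), by either adjustment. Of the flavonoid probes 5 passed on the positive and 1 on the negative side, 6 adjusted over the list alone (mean 3.21, adjusted p = 0.0173; adjusted p = 0.619 with an estimated correlation). By camera the other 6 lists did not pass, photosynthesis with an adjusted p of 0.0597; by fry detoxification did (adjusted p = 0.0071; by camera 0.389). In all, 6763 probes passed, 3464 on the positive and 3299 on the negative side. Without AK069096 replicate 1 the count was 1351, without replicate 2 it was 2193, and with quantile normalization 4066.

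Against the other 5 lines, AK069096 stood out on the positive side with the alpha-amylase gene AMY1 (difference 1.73 ± 0.19, n = 2 arrays, adjusted p = 0.0161, with a line mean of 1.29 and other lines at -0.44), the phosphatase gene SAL2 (1.27), CCS, the copper chaperone gene of superoxide dismutase (1.1), and the linker histone gene HIS1-3 (0.89). For SAL2 the line mean was only 0.36, below the 0.75 of AK073112. Its difference comes mainly from AK073675 (-1.60), AK065297 (-1.98) and AK073210 (-1.57). THI2.1 (-1.26, with AK069096 at -0.80, AK073210 at 2.58 and the other 4 lines between -0.49 and 0.27), TRM31 (-1.13), the vacuolar sugar transporter gene SWEET16 (-0.97) and CHL, a chloroplast lipocalin gene (-0.74), lay on the negative side. The line mean of CHL was -1.59 in both AK069096 and AK073112. No gene list passed by camera or fry, the nearest by camera being chlorophyll synthesis (adjusted p = 0.0747), with 0 genes past the threshold over all probes and 4 adjusted over the list alone. In all 247 probes passed, 151 on the positive and 96 on the negative side, and each array left out in turn moved the count. It was 5713 without AK073112 replicate 2 and 3154 without AK073112 replicate 1, and it lay between 29, without AK102323 replicate 1, and 74, without AK069096 replicate 2, for the other arrays. Quantile normalization gave 42, with 50.0% on the positive side against 61.1%, the replicate block 53 and array weights 3606. AK073112 replicate 2 correlated across probes with the AK069096 arrays at r = 0.799 and 0.816, close to the 0.805 of these 2 arrays with each other.

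Among genes with a symbol, AK073112 differed from the other lines most in PDF1.2, a defensin gene induced by jasmonate and ethylene. It stood at 4.2 ± 0.79 against Col-0 (n = 2 arrays, adjusted p = 0.00964), with 5.88 on replicate 1 and 2.52 on replicate 2, and at 4.54 against the other 5 lines (adjusted p = 0.0375). Also on the positive side against Col-0 were DFR (4.90), UF3GT (4.18), AT5MAT (2.29), UGT78D2 (2.27), SWEET13 (2.17), UGT71C3 (2.11) and the MADS-box gene AGL19 (2.01). Their means join unlike arrays, and leaving out one array gives the value of the other. Replicates 1 and 2 had 3.26 and 6.54 for DFR, 0.66 and 3.92 for AT5MAT, 1.3 and 3.24 for UGT78D2, 0.79 and 3.55 for SWEET13, and 3.0 and 1.03 for AGL19. On the negative side were MSRB6 (-2.36), the Mediator subunit gene MED10A (-2.14), BZIP61 (-1.84), COR27, which links cold and clock (-1.82), UGT73B1 (-1.68), CHL (-1.59), the U-box gene PUB15 (-1.58) and BGLU16 (-1.52), with replicates 1 and 2 at -0.90 and -3.82 for MSRB6, -1.16 and -2.51 for BZIP61, and -0.61 and -2.43 for BGLU16. Against the other 5 lines SAL2 (1.73), the iron-sulphur assembly gene SUFE2 (1.37) and ATPMEPCRD, a pectin methylesterase gene (1.35), lay on the positive side, and PUB15 (-1.37), COR27 (-1.17), CHL (-0.74) and F2KP, a regulator of sucrose synthesis (-0.62), on the negative side. AK069096 lay on the same side of 0 for SAL2 (line mean 0.36, against 0.75 in AK073112) and CHL (-1.59 in both lines).

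Among the lists, 4 of 6 flavonoid probes passed on the positive and 1 on the negative side in AK073112, 6 adjusted over the list alone (mean 2.41, camera adjusted p = 0.0173). In chlorophyll synthesis 3 of 4 genes passed on the negative side, by either adjustment (mean -0.94, adjusted p = 0.0149), and in detoxification 2 of 3 on the positive side, by either adjustment (mean 0.82, adjusted p = 0.0396). All of these had an adjusted p = 0.619 with an estimated correlation. Replicates 1 and 2 had means of 1.35 and 3.47 for the flavonoid list, -0.49 and -1.39 for chlorophyll synthesis, and 1.18 and 0.47 for detoxification, so each mean moves by over 1.5 times without one of them. By fry cold response also passed (adjusted p = 0.0446; by camera 0.475). Against the other 5 lines no list passed by camera, while detoxification did by fry (adjusted p = 0.031; by camera 0.0934). Against Col-0 4366 probes passed, 2213 on the positive and 2153 on the negative side, and against the other 5 lines 599, with 334 and 265. The replicates of this line correlated at 0.352, below the 0.586 or more of every other line. Array weights left 4 probes against Col-0 and 0 against the other lines, and quantile normalization 2574 and 200. Without AK073112 replicate 1 the counts were 6677 and 2468. Against the other lines the count was 4746 without AK073112 replicate 2 and between 133, without AK102323 replicate 2, and 392, without AK073675 replicate 1, for the remaining arrays, each of which moved it.

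**Figure D3:**
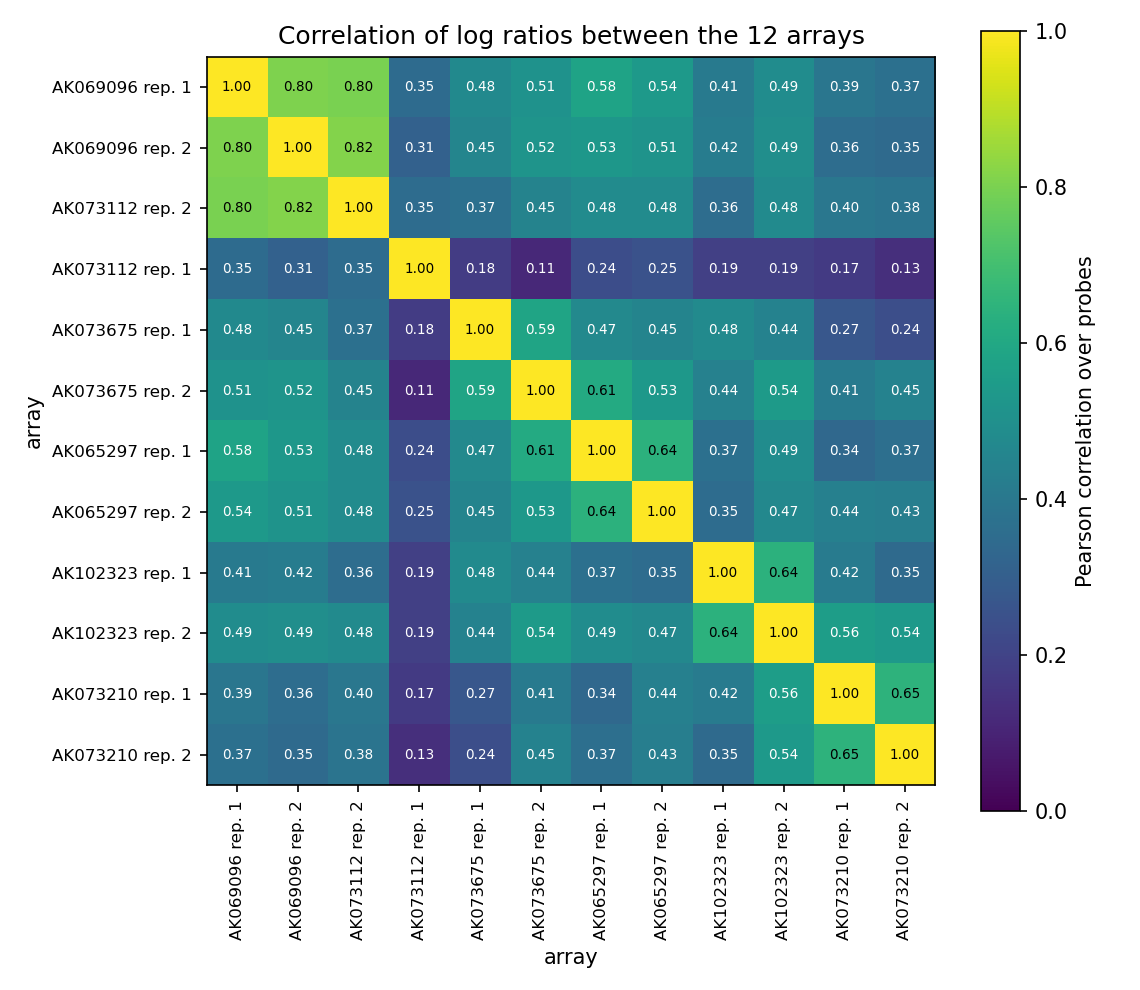
Pearson correlation of the log ratios over probes for each pair of the 12 arrays (both axes), with the value in each cell. AK073112 replicate 2 correlates at 0.80 and 0.82 with the AK069096 arrays, and AK073112 replicate 1 at 0.35 or less with any other array.

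AK073675 had UF3GT at 2.88 ± 0.52 (n = 2 arrays, adjusted p = 0.0252), followed by BGLU46, a monolignol glucosidase gene (1.85), UGT71C3 (1.29), HIS1-3 (1.04), the light signalling gene HYH (1.04), the alkenal reductase gene AER (0.86; 1.15 on replicate 1 and 0.57 on replicate 2), CaS, a thylakoid calcium sensor gene (0.86), and UGT73B5 (0.81). On the negative side were MSRB6 at -2.66 ± 0.59 (n = 2, adjusted p = 0.0442), the triterpene synthase gene LUP5 (-1.93), AMY1 (-1.80), the cyclophilin gene SQN (-1.63), SAL2 (-1.60), CYP79A2 (-1.53), the acyltransferase gene GLC (-1.32) and the endoglucanase gene GH9C3 (-1.30). One flavonoid probe passed over all probes and 5 adjusted over the list alone (mean 1.67, camera adjusted p = 0.00673). In chlorophyll synthesis 0 genes passed over all probes and 3 adjusted over the list alone (mean -0.61, adjusted p = 0.0173; by fry 0.0708). By fry detoxification passed (adjusted p = 0.0147; by camera 0.163). The flavonoid and chlorophyll lists had an adjusted p = 0.619 with an estimated correlation. In all 1235 probes passed, 590 on the positive and 645 on the negative side, and each array left out in turn moved the count. It was 4053 without either AK073112 array and 20 without AK073675 replicate 1, and between 511, without either AK102323 array, and 775, without either AK073210 array, for the others. Quantile normalization gave 3724.

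Against the other 5 lines limma passed 0 probes for AK073675, with 2409 at an unadjusted p under 0.05, and no gene list passed by camera or fry. Other settings gave 16 probes with quantile normalization, 4 with exact zeros as missing, 4 with probes averaged per locus, 12 without both AK073112 arrays, and 0 with the replicate block, array weights or a robust spread. Single arrays moved it to 765 without AK073112 replicate 1, 41 without AK073112 replicate 2, 10 without AK073675 replicate 2 and 5 without AK073675 replicate 1.

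AK065297 had UF3GT at 2.72 ± 0.52 (n = 2 arrays, adjusted p = 0.0273), the RING finger gene ATL43 at 1.66, the lipase gene SDP1-LIKE at 1.5, HIS1-3 at 1.38, GH3.1, of the auxin-conjugating family, at 1.3, the U-box ligase gene PUB22 at 1.05, COR15A at 1.02 and the organic cation transporter gene OCT4 at 1.01. The negative side held LUP5 at -2.33 ± 0.40 (n = 2, adjusted p = 0.0206), BGLU19 at -2.12, SAL2 at -1.98, the carboxypeptidase-like gene scpl16 at -1.68, AGL67 at -1.55 (replicates 1 and 2 at -1.02 and -2.08), the pyruvate decarboxylase gene PDC3 at -1.38, PUB15 at -1.36 and the glutaredoxin gene GRX480 at -1.34. The flavonoid list passed with 1 probe over all probes and 5 adjusted over the list alone (mean 1.69, camera adjusted p = 0.00322; adjusted p = 0.619 with an estimated correlation). No other list passed by camera, chlorophyll synthesis having an adjusted p of 0.0709; by fry detoxification did (adjusted p = 0.0416; by camera 0.26). In all 1360 probes passed, 649 on the positive and 711 on the negative side. The count was 3984 without either AK073112 array, 653 without either AK102323 array, 296 without AK065297 replicate 1 and 74 without replicate 2. Quantile normalization gave 3007 and array weights 6651.

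Only 2 probes set AK065297 apart from the other 5 lines, both on the negative side (differences -3.24 and -1.25, adjusted p = 0.0495 and 0.00384) and neither with a gene name. They lie outside the rule for named genes and are given because the count is small. Single arrays moved this count to 778 and 57 without AK073112 replicates 1 and 2, to 93 and 22 without AK065297 replicates 1 and 2, to 5 and 4 without AK069096 replicates 1 and 2, and to 1 without either AK102323 array. Quantile normalization gave 22 and array weights 257.

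AK102323 had UF3GT at 3.09 ± 0.52 (n = 2 arrays, adjusted p = 0.021), DFR at 2.91, UGT78D2 at 1.80, HYH at 1.67, the xyloglucan endotransglucosylase gene XTH29 at 1.62, NAI1, a regulator of ER bodies, at 1.33, LBD16, known from lateral root initiation, at 1.2 and the tetraspanin gene TET9 at 1.11 (replicates 1 and 2 at 1.49 and 0.73). CYP79A2 led the negative side at -1.75 ± 0.22 (n = 2, adjusted p = 0.00817), followed by the microtubule-associated gene SP1L4 at -1.47, the embryogenesis regulator BBM at -1.23, the folate synthesis genes FOLB3 at -1.14 and FOLB1 at -0.93, COR15B at -1.10, the endoglucanase gene GH9B18 at -1.10 and COR27 at -1.0. In the flavonoid list 4 probes passed, 5 adjusted over the list alone (mean 2.12, camera adjusted p = 0.000646). Of the chlorophyll synthesis genes 0 passed over all probes and 1 adjusted over the list alone (mean -0.46, adjusted p = 0.0411; by fry 0.152). Both had an adjusted p = 0.619 with an estimated correlation. In all 870 probes passed, 427 on the positive and 443 on the negative side. The count was 3097 without either AK073112 array, 548 without either AK065297 array, 96 without AK102323 replicate 2 and 19 without replicate 1. Quantile normalization gave 3698 and array weights 6810.

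Against the other 5 lines 17 probes passed in AK102323, 10 on the positive and 7 on the negative side. Of these, 7 have a gene, all known by locus code alone and therefore outside the rule for named genes. No gene list passed by camera, while detoxification did by fry (adjusted p = 0.031; by camera 0.0747). Every array but AK073210 replicate 1 moved the count. It was 658 and 101 without AK073112 replicates 1 and 2, 30 without AK102323 replicate 2, 0 without AK102323 replicate 1 or AK065297 replicate 2, 4 without AK065297 replicate 1, and between 5 and 10 without either AK069096 array, either AK073675 array or AK073210 replicate 2. Quantile normalization gave 248, array weights 563, exact zeros as missing 30 and the replicate block 4.

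In AK073210 the gene with a symbol farthest from the other lines was VGD1, a pectin methylesterase gene of pollen tubes. It had a log2 ratio of 3.85 ± 0.34 against Col-0 (n = 2 arrays, adjusted p = 0.00192) and a difference of 3.93 ± 0.37 from the other 5 lines (adjusted p = 0.0056), whose mean was -0.08. Its neighbour in the family, VGDH1, stood at 2.74 and 3.15, the thionin gene THI2.1 at 2.79 above the other lines, and CES, a bHLH gene of brassinosteroid signalling, at 2.70 and 2.64. Further genes on the positive side against Col-0 were UF3GT (3.72), AT5MAT (3.39), DFR (3.11), the carnitine transporter gene OCT1 (3.1) and the glutathione transferase gene GSTU15 (2.88). MSRB6 (-3.29), PYK10, a beta-glucosidase gene of ER bodies (-2.29), PRA1.F1, of a family of Rab acceptors (-1.80; replicates 1 and 2 at -1.15 and -2.46), SAL2 (-1.57), COR15B (-1.39), SP1L4 (-1.28), CYP79A2 (-1.17) and PORB (-1.09) lay on the negative side. Against the other lines SP1L4 (-0.90), AGL28 (-0.86), the calmodulin-like gene CML23 (-0.61) and DJ1F (-0.43) did.

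**Figure D4:**
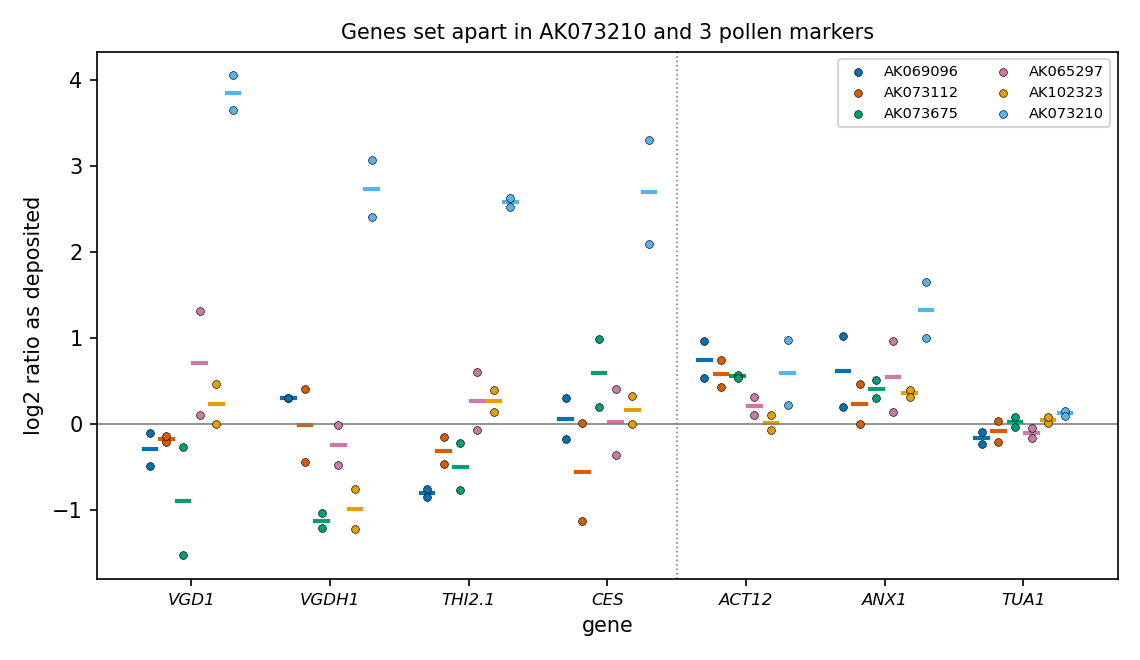
Log2 ratios as deposited (y axis) of 7 genes (x axis), with a point for each array, coloured by line, and a bar at each line's mean. Left of the dotted line are the 4 genes with a symbol that lie farthest on the positive side in AK073210 against the other 5 lines (genes known by locus code alone are not shown); right of it are the pollen markers ACT12, ANX1 and TUA1, whose differences of 0.18, 0.89 and 0.18 did not pass.

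In AK073210 the flavonoid list passed with 5 probes on the positive side, by either adjustment (mean 2.46, camera adjusted p = 0.00062). Photosynthesis passed with 1 gene on the negative side, 3 adjusted over the list alone (mean -0.65, adjusted p = 0.0286; by fry 0.0951), and chlorophyll synthesis with 1 gene, 2 adjusted over the list alone (mean -0.56, adjusted p = 0.0411; by fry 0.0951). All 3 lists had an adjusted p = 0.619 with an estimated correlation, and no list passed against the other 5 lines by camera or fry. Against Col-0 2082 probes passed, 1109 on the positive and 973 on the negative side. That count was 4972 without either AK073112 array, 399 without AK073210 replicate 1, 759 without replicate 2 and 3227 with array weights. Against the other lines 311 passed, 228 on the positive and 83 on the negative side, and 72 probes lay more than 1 above all other arrays on both arrays of this line. The 311 became 1183 and 657 without AK073112 replicates 1 and 2, 103 without AK073210 replicate 1, 187 and 186 without the AK069096 arrays, 171 and 192 without the AK065297 arrays, 176 without AK073675 replicate 1 and 182 without AK102323 replicate 1.

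Across the 6 lines 9343 probes passed against Col-0 in at least 1 line, and 192 passed on opposite sides in 2 lines. No test of the difference between lines was made for the lists beyond the comparisons with the other 5 lines, in none of which a list passed by camera (lowest adjusted p = 0.0747); by fry detoxification passed in 2 of them. For 21 of 104 results of the set test the mean, the median and the direction of the test differed in sign, and none of these was past the threshold. The flavonoid list's median against the other lines changed sign under quantile normalization in AK073112, AK065297, AK102323 and AK073210. The 16 results past the threshold had adjusted p from 0.445 to 0.619 with an estimated correlation, and fry kept 12 of them.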

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

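The tests of a wrong label, of an odd array, of a shared dye effect and of a shared Col-0 RNA were chosen after the results they weigh had been seen. For the pollen markers the bound was written before those markers were looked at, but after VGD1 and its neighbours had been seen in AK073210.

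Ratios differed between lines, by a direct test of each line's ratio against the mean of the other 5, at 247 probes for AK069096, 599 for AK073112, 2 for AK065297, 17 for AK102323 and 311 for AK073210. Whether all arrays had the same Col-0 RNA is not given in the sources used here. A difference of ratios can therefore lie in the line or in the Col-0 RNA set against it. Genes behind these differences included AMY1 for AK069096, PDF1.2 for AK073112, and VGD1 and THI2.1 for AK073210. The AK073112 arrays are unlike (r = 0.352), with PDF1.2 at 5.88 on replicate 1 and 2.52 on replicate 2. The SE of that difference comes from a spread shared by all lines. An outlier test was not made, since each line has 2 arrays.

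AK073112 replicate 2 correlated more closely with both AK069096 arrays than with its own replicate. The split of these 4 arrays by line parted 313 probes by more than 0.5, against 378 and 304 for the crossed splits, a ratio of 0.828 to the larger one. The ratio was above 1.5 for 14 of 15 pairs of lines, AK069096 and AK073112 being the exception. A wrong label on one array may therefore lie behind the resemblance. AK073112 replicate 1 also stood apart, since its highest correlation with any array was 0.352 while every other array reached at least 0.586. An odd replicate 1 may lie behind the low correlation within the line. By itself it would not explain the 0.799 and 0.816 of replicate 2 with the AK069096 arrays. Other pairs of arrays from different lines reached at most 0.611. A wrong label on replicate 2 would likewise leave replicate 1 without a true replicate, so its low correlation does not separate these explanations. A true likeness of the 2 lines was not tested and also stays open, and the values do not say which array would carry a wrong label.

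Ratios shared by all 6 lines, with DFR and UF3GT on the positive and MSRB6 on the negative side, cannot be told apart from one dye effect on every array or one Col-0 RNA shared by all arrays, because no array swaps the dyes or compares Col-0 with Col-0. A pure dye effect of one size on every array would leave the flavonoid list's mean alike in all lines. By the exact pairing test that mean differed between lines with a p of 0.303 over all 12 arrays and of 0.00741 over the 10 without AK073112. Among these 10 the standard deviation of the ratios ran from 0.40 (AK102323 replicate 2) to 0.66 (AK069096 replicate 1). A dye effect that scales with this spread would also give unequal means. The list's means followed the spread only in part. AK069096 replicate 1 had 3.38, but AK102323 replicate 2, with the lowest spread, had 2.36, above the 1.58 of AK065297 replicate 2 (spread 0.50). Scaling with the spread alone would not give this order. With quantile normalization the list's medians against Col-0 still ran from 1.91 (AK073112) to 3.39 (AK102323). The exact pairing test over all 12 arrays gave a p of 0.303, so it cannot decide. Quantile normalization changed the sign of the list's median against the other lines in AK073112, AK065297, AK102323 and AK073210. For a shared Col-0 RNA, the median covariance between arrays of different lines was 0.109, within the simulated values for unchanged lines (up to 0.115), and 3222 probes with every array on one side did not exceed them (3239 to 3386), but 166 past the threshold in every line (20 to 40) and 10944 for all lines together (9614 to 9904) did. Without AK073112 all of these exceeded them: a covariance of 0.109 (up to 0.0860), 5015 probes with every array on one side (3792 to 4038), 1110 in every line (4 to 23) and 11957 together (8075 to 8432). The observed covariance was the same with and without AK073112, and only the simulated values fell. The median correlation between lines went the other way. It lay below every simulated value, at 0.431 with all lines (0.487 to 0.514) and at 0.448 without AK073112 (0.477 to 0.513). Because the spread of Col-0 in the simulations was assumed, the question stays open, as does an effect common to transformants, which was not tested separately.

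Genes set apart in AK073210 included several of pollen: besides VGD1 and VGDH1 these were AT3G07850 (5.92), AT3G14040 (4.85) and AT5G15110 (2.67), chosen after their values were seen. If pollen content of the tissue differed, other pollen genes should lie on the same side. The 9 markers not seen before had a median difference of 0.18, above the 95th percentile of 0.13 for 10000 random lists, with 7 of 9 positive, so pollen or flower tissue may have contributed. The size is small, however, and none passed alone, with ANX1 at 0.89, AT59 at 0.60, ACT12 and TUA1 at 0.18 and AGL104 at -0.11. Random lists hold unrelated probes, while markers of one tissue can move together, so the 95th percentile may be too low a bound. AT59 was at exactly 0 on most arrays, and its difference rests mainly on 0.492 on AK073210 replicate 1 and -2.505 on AK065297 replicate 1. AGL104 had 0 and -0.807 on AK073210 replicates 1 and 2. An effect of the rice cDNA on the pollen genes was not tested and stays open, as does a difference in the Col-0 RNA of the AK073210 arrays.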

How the results depend on the processing

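Leaving out both AK073112 arrays was chosen after the data were seen; the other alternatives were not. Counts are of probes past an adjusted p of 0.05, and lines are in the order AK069096, AK073112, AK073675, AK065297, AK102323, AK073210 unless named. Except where the construction shows it, the cause was not tested.

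Every array already has a median of 0, so centring changes no value and tests nothing. Allowing missing values left 13 of 13 counts within 1.5 times. Quantile normalization, which gives all arrays one spread, left 3 of 13 within it. Against Col-0 the first 5 lines had 4066, 2574, 3724, 3007 and 3698 probes, and against the other 5 lines 42, 200, 16, 22 and 248. The positive share moved from 61.1% to 50.0% for AK069096 and from 0% to 45.5% for AK065297 against the other lines.

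With a replicate block 11 of 13 counts stayed within 1.5 times, AK069096 having 53 and AK102323 4 against the other lines. Nothing in the labels pairs arrays by replicate number. Deviations of arrays of the same number correlated between -0.0680 and 0.175 (median 0.0326), above 0.1 in 2 of 15 pairs of lines. On average 10 of 12 arrays were closer to arrays of their own number. In that count the 2 arrays of a line always go together, because their deviations mirror each other. A weak link by number is not excluded. A robust spread moved only AK065297 against the other lines, to 1. Array weights gave AK073112 4, AK065297 6651, AK102323 6810 and AK073210 3227 against Col-0, and AK069096 3606, AK073112 0, AK065297 257 and AK102323 563 against the other lines. Exact zeros as missing gave AK073675 4, AK065297 0 and AK102323 30 against the other lines.

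Averaging probes per locus drops the probes without a gene, so fewer were tested. It gave 3300, 2098, 625, 489, 346 and 917 against Col-0, 4996 for all 6 lines, and AK069096 130, AK073112 270, AK073675 4, AK065297 0 and AK073210 140 against the other lines. A minimum absolute log2 ratio of 1 left 1608, 896, 311, 432, 262 and 654 against Col-0, 411 for all 6 lines, and AK069096 92, AK073112 155 and AK073210 191 against the other lines. With only the 2 arrays of the line, limma passed 0 probes in each of the 6 lines, with 1 residual degree of freedom.

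Without both AK073112 arrays the counts against Col-0 were 4053 for AK073675, 3984 for AK065297, 3097 for AK102323 and 4972 for AK073210, and these included all of their 1235, 1360, 870 and 2082 probes. Against the other lines they were 5528 for AK069096, 12 for AK073675, 38 for AK065297, 56 for AK102323 and 482 for AK073210, the last including 251 of its 311.

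Leaving out each array in turn, with a lone array assumed to vary like the other lines, gave ranges against Col-0 of 1351 to 9303, 3309 to 6677, 20 to 4053, 74 to 3984, 19 to 3097 and 399 to 4972. Against the other lines they were 29 to 5713, 133 to 4746, 0 to 765, 1 to 778, 0 to 658 and 103 to 1183. All 6 lines together gave 9217 to 12667, within 1.5 times of 10944.

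Of 132 results for named genes none reversed. Against Col-0 the rule takes only genes with all arrays of the comparison on one side, so leaving out arrays could not reverse them. Centring and the replicate block leave the ratios as they are, so the sign is not tested there either. Quantile normalization and the replicate block each kept 114 past the threshold. Leaving out an array ended between 4 calls (AK073112 replicate 1) and 42 (AK102323 replicate 1), and without both AK073112 arrays 107 of 108 stayed. Of 16 list results fry kept 12 and an estimated correlation 0. Signal over background could not be examined, because channel intensities were not used here.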

Other observations

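The families and the comparisons between single arrays in this part were chosen after data had been seen. For all 6 lines 50.9% of all probes passed, so a family count near that share does not set the family apart. Tubulin genes lay on the negative side for all 6 lines, with 6 of 10 past the threshold (n = 12 arrays), by either adjustment: TUB5 at -0.64, TUA5 at -0.42, TUB1 at -0.37, TUA3 at -0.26, TUB9 at -0.18 and TUA6 at -0.15 (camera adjusted p = 0.01; adjusted p = 0.479 with an estimated correlation). The family also passed in AK069096 (0.021), AK073675 (0.00322) and AK065297 (0.0408, by fry 0.0879), each with an adjusted p = 0.774 with an estimated correlation. It did not pass by camera in AK073112, AK102323 or AK073210 (adjusted p = 0.0786, 0.256 and 0.741). In AK073210 the mean was -0.04, with 0 genes past the threshold. Among 45 glycosyltransferase genes of the UGT family 20 passed on the positive and 8 on the negative side for all 6 lines, 30 adjusted over the family alone, with UGT78D2 (1.86), UGT71C3 (1.23) and UGT72E1 (0.86) against UGT73B1 (-0.93) and UGT73C7 (-0.74). By camera this family did not pass there (adjusted p = 0.0859, by fry 0.000254) but did in AK073112, against Col-0 (adjusted p = 0.0138, and 0.774 with an estimated correlation) and against the other 5 lines (adjusted p = 0.0431, 0.849 with an estimated correlation, and 0.0701 by fry). In AK069096 against Col-0 14 UGT genes passed on the positive and 8 on the negative side. There the family passed by fry (adjusted p = 0.00421) but not by camera (adjusted p = 0.243). No median of the tubulin or UGT family against Col-0 changed sign under quantile normalization.

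For all 6 lines, where 50.9% of all probes passed, the other 9 families did not pass by camera. By fry beta-glucosidases (adjusted p = 0.000254), cellulose synthase-like genes (0.000369) and cytochromes P450 (0.00176) did. Their genes past the threshold, positive and negative, were 3 and 7 of 19 for cytochromes P450 (adjusted p = 0.264), 2 and 6 of 16 for beta-glucosidases (0.264; BGLU16, BGLU44 at -0.75 and BGLU19 at -0.75), 3 and 4 of 13 for glutathione transferases (0.622; GSTU15 at 1.64) and 5 and 2 of 12 for expansins (0.836; EXPA8 at -1.37, EXPA15 and EXPA9 at 0.78). They were 2 and 3 of 11 for SWEET sugar transporters (0.836), 1 and 1 of 11 for the auxin-induced IAA and GH3 genes (0.836), 2 and 2 of 9 for WRKY factors (0.836), 1 and 2 of 8 for xyloglucan endotransglucosylases (0.622; XTH29 at 0.68) and 0 and 4 of 8 for cellulose synthase-like genes (0.441; CSLC04 at -0.68). Glutathione transferases, expansins and SWEET genes had means of 0.00, 0.00 and 0.14 with medians of -0.14, -0.14 and -0.07, WRKY factors a mean of 0.01 with a median of 0.00, and the auxin-induced genes a mean of -0.03 with a median of 0.02.

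AK073675 replicate 1 and AK102323 replicate 1, arrays of 2 lines, shared 25 probes more than 1 below all other arrays. A list of 8 tapetum and anther wall genes had medians of -2.52 and -1.53 on these arrays, 0.46 and 0.74 on the other arrays of the same lines, and 1.31 and 1.49 on the AK073210 arrays. None of the 8 passed in AK073210 against the other 5 lines, though the differences of all 8 were positive; 6 of the 8 had been seen before the list was written, so neither this sign nor these medians test it. The 14 mature pollen genes had medians of 0.37 and 0.76 on the AK073210 arrays, 5 of them having been seen before the list was written.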
